A study of Mus musculus with 20 samples.

How the data were processed

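Poly(A)-selected, stranded RNA libraries from ovarian antral follicles of 20 CD-1 mice were sequenced for 101 cycles from 1 end on 1 lane. Per the labels, reads had their 3' adaptors removed. The submitters' processing notes list FastQC 0.11.8, Salmon 1.2.0, edgeR, limma, R 4.1.2 and the mouse build GRCm39. Salmon assigns reads to transcripts and shares a read that fits several of them by estimation. How transcripts were summed to genes, which annotation was indexed and how the authors' model was built are not given in the sources used here.

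The deposited table holds estimated counts per gene, not normalised, for 39253 genes in the 20 mice. These values are not whole numbers, and near-identical genes and pseudogenes share reads in them. They were rounded to whole numbers, which changed a library total by a median of 79.96 counts. The column headers of the table name the experiment and group of each mouse. A deposited table of results gives, per the file headers, the average log2 expression over the mice, raw and adjusted p-values of each comparison, a score over the 3 groups (an F statistic) and signed linear fold changes, all computed by the authors. It lists the 18169 genes that the authors marked as kept, and it was used here only to set its calls and fold changes beside those recomputed from the counts.

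Library totals ran from 39.9 M to 67.5 M estimated counts. Spread between mice, not counting error, limited the precision at this depth. Pairs of libraries within a group differed by a chi-square per gene of 22.5 to 156 over 65 pairs, so no library was a copy of another of its group.

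Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by its expression filter with the group as the factor, which left 17810 genes, all among those kept by the authors, and library sizes were scaled by trimmed means (TMM). A quasi-likelihood model with robust dispersion was fitted to all 20 mice with 1 mean per group, and each contrast was tested by the quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment over the tested genes at 0.05. The main model has no term for experiment, because the submitters combined the controls. A second model with a mean for each group in each experiment gave the comparisons of each dose with its own controls, the difference between those effects and the difference between the control sets. SE is that of the log2 change in this model, from its F statistic. Standard deviations are over mice, on CPM computed from TMM-scaled library sizes.

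Before the data were examined, the groups, tests, alternatives, gene lists and the rule for named genes were fixed. That rule took, for each contrast, up to 8 genes per direction with the largest change among those that passed with a mean of at least 2 CPM and all mice of the first group on 1 side of the median of the other, and up to 4 members with the smallest p of each list described. Of the 33 lists, 32 had at least 3 tested members. No gene encoded by mitochondrial DNA was among the tested genes, so the list of those genes got no test. Lists were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 32 lists, and beside it with an estimated correlation and with fry, a test of whether a list's genes move on balance in 1 direction. Fry gave no list an adjusted p under 0.05 in the comparisons of exposed mice. Values called adjusted over the list alone use the members of a list as the family. A positive or negative member is one with that sign of log2 change, whatever its p.

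The following were added after the data had been seen: camera over 2806 ontology and pathway terms of 15 to 500 genes in the authors' annotation, an exact permutation test of each list's mean log2 CPM per mouse (prior count 2, two-sided, all splits of the mice), splits that exchanged mice within 1 experiment alone, the effect of either dose with experiment as a term, and surrogate variables without a limit on their number. CPM in the tests per mouse were first scaled by library totals and then by TMM, after values had been seen. The rule for reading some of the explanations in the closing section was also matched to its written form at that stage, which changed no reading. The bounds for a rise of immediate early genes in most exposed mice and for tissue from outside the follicle were made stricter after their values had been seen, which left both explanations open.

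Alternatives replaced 1 choice at a time: DESeq2 size factors or upper-quartile factors, no filter on low counts or at least 1 CPM in at least 5 mice, DESeq2 1.42.0, limma-trend or limma-voom, only the groups compared, the controls of the own or the other experiment, replicate number as a block, up to 3 surrogate variables from sva 3.50.0, a fold threshold of 1.2, and each mouse left out in turn. The DESeq2 test was an exception. It started from the unfiltered counts with its own size factors, filter and adjustment, so several choices changed together. Counts of genes, lists and terms were set beside those of 100 random splits of the same mice into groups of the same sizes, the real split included. Correlations across mice were computed on deviations from the group means, with 100000 permutations. The expected correlation of the doses through their shared controls came from 20 simulated data sets.

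The gene test was tested on simulated data with 100 genes changed 1.5-fold and 100 changed 2-fold. At 10 mg/L it recovered 50% and 66% of them with 9 false calls, at 500 mg/L 50% and 69% with 5, between the doses 37% and 73% with 7, between the control sets 37% and 65% with 4, for the difference between dose effects 17% and 53% with 1, and for either dose 59% and 76% with 6. With so many genes changed, the adjustment sets a laxer cut-off on p than when few change. Recovery would thus be lower if only a few genes changed. The simulated mice had no difference between experiments, and comparisons of a dose with its own controls were not simulated. The permutation test of lists, with 5 mice against 10, found a raised list in 20 of 20 simulated data sets and called 3 of 640 unchanged ones. The simulated genes of a list varied independently between mice. Members of real lists can move together, so the power of the test on real lists is not known from this. The reference annotation at hand was of an older build than the authors', so no coordinates are given, and it served for gene names, gene order and transcript length.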

Results

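Iodoacetic acid forms as a by-product when drinking water is disinfected. Female CD-1 mice, an outbred stock, drank water with iodoacetic acid at 10 mg/L or 500 mg/L, or water alone, for 35 days from day 40 of life. Antral follicles of 220 to 400 µm, in which granulosa and theca cells surround an oocyte, were dissected from the ovaries in diestrus at 75 days. Each library held the follicles of 1 mouse, 30 to 40 of them, so the 20 libraries were 20 animals. The control group had 10 mice, and each dose had 5. The animals came from 2 experiments run a month apart: experiment 1 held control replicates 6 to 10 and the mice at 500 mg/L, and experiment 2 held control replicates 1 to 5 and the mice at 10 mg/L.

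Estimated counts per library summed to 41.7 M to 51.0 M in the controls, 39.9 M to 51.5 M at 10 mg/L, and 43.1 M to 67.5 M at 500 mg/L (M for mega). After a filter on low counts, 17810 genes were tested. Expression of a gene typically varied between mice of a group by 24.98% (the biological coefficient of variation). The first principal component held 13.6% of the variance, and the second held 9.43%. Expression is given below in CPM (read counts scaled to a common library size), with the SD over mice, and changes are given as log2 ratios with their standard error (SE). Each dose was compared with the 10 controls of both experiments, as the submitters combined them, and then with the 5 controls of its own experiment.

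The first comparison asked which follicle mRNAs differed after 10 mg/L. Mid1, an X-linked gene for a microtubule-binding E3 ubiquitin ligase, doubled: it reached 43.2 ± 8.63 CPM (SD, n = 5) against 21.5 ± 3.81 CPM in the controls (SD, n = 10). Its log2 change was 1.00 (SE 0.16; edgeR adjusted p = 0.0471), and it was higher in 5 of 5 exposed mice than in any control, with a lowest exposed value of 31.99 CPM and a highest control value of 27.5 CPM. No lower gene passed. At an unadjusted p under 0.05 edgeR counted 1108 genes, 560 of them lower, where chance alone gives 890.5 in all. DESeq2 called 8 genes, and limma-trend and limma-voom called 0. Against the controls of experiment 2 alone, Mid1 was higher by 0.98 on the log2 scale (SE 0.19) but did not pass (edgeR adjusted p = 0.297), nor did any other gene (0 by edgeR, with 1148 at an unadjusted p under 0.05). Its call also depended on single libraries: it passed in 5 of the 20 fits that left out 1 library each, with adjusted p from 0.00731 to 0.289 and a log2 change from 0.92 to 1.10.

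Several gene groups fixed before the data were examined shifted together at 10 mg/L, although no member passed over all genes. Markers of endothelial cells, which line the vessels of the theca layer, rose as a group by a median of 0.31 on the log2 scale, with 13 of 13 members positive (camera adjusted p = 7.21e-10). With an estimated correlation between genes the adjusted p was 0.595. Adjusted over the list alone, 7 of the 13 markers passed, among them Pecam1 at 0.31, the TGF-beta co-receptor Eng at 0.42, the junction protein Esam at 0.36 and the receptor Tie1 at 0.40, and over all genes 0 of 13 did. The score of this list per mouse, the mean log2 CPM of its members, was above the control median in 4 of 5 exposed mice, and the difference of 0.27 had an exact two-sided permutation p of 0.0490 (adjusted p = 0.626 over 32 lists). Scores of markers of stroma, pericytes and leukocytes, other cells that can adhere to a dissected follicle, differed from all controls by 0.109, 0.0262 and −0.123 (exact permutation p = 0.507, 0.883 and 0.647). Against the controls of experiment 2 these scores were higher by 0.115, 0.0813 and 0.111 (exact permutation p = 0.563, 0.667 and 0.714), where the endothelial score was higher by 0.287 (exact permutation p = 0.103).

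Immediate early genes, which encode transcription factors and feedback regulators induced within minutes of a stimulus, also rose as a group at 10 mg/L (median log2 change 1.01, 17 of 18 members positive, camera adjusted p = 1.08e-08). The adjusted p was 0.710 with an estimated correlation. None of the 18 passed, either adjusted over the list alone or over all genes, and 12 were higher at an unadjusted p under 0.05 by edgeR, with log2 differences of 2.92 for Fosb, 2.18 for Fos, 1.14 for Ier2 and 1.45 for Junb. Fos ranged from 25.5 to 643 CPM among the 5 exposed mice and from 31.3 to 121 CPM among the 10 controls. In list scores per mouse, 4 of 5 exposed mice lay above the control median, and the mean of all 5 exceeded that of the controls by 0.80 (exact two-sided permutation p = 0.00932, adjusted p = 0.298). Against the controls of experiment 2 alone that score was higher by 0.761 (exact two-sided permutation p = 0.0873).

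Luteal cell markers rose as a list by a median of 0.41 at 10 mg/L (12 of 14 positive, camera adjusted p = 0.00648, and adjusted p = 0.738 with an estimated correlation). Their members with the smallest p included Sfrp4, a secreted Wnt antagonist, at 0.96, the prostaglandin receptor Ptgfr at 0.87 and the growth factor Vegfa at 0.26, and 0 of 14 passed over all genes or adjusted over the list alone. This list rested on a single library, since without replicate 4 at 10 mg/L its adjusted p was 0.179, its median 0.10 and Ptgfr 0.51. Without control replicate 7 the median was 0.66 and Ptgfr 1.43, and without replicate 1 at 10 mg/L Vegfa was 0.16. Against the controls of experiment 2 the luteal score per mouse was higher by 0.790 (exact two-sided permutation p = 0.103). The luteal scores of the control sets themselves differed by 0.671, higher in experiment 1. Extracellular matrix genes, among them Mmp9 at 0.64, Eln at 0.34 and Col1a1 at 0.29, had a median of 0.17 (adjusted p = 0.0312, and adjusted p = 0.839 with an estimated correlation), and 0 of 22 passed over all genes or adjusted over the list alone. Without replicate 2 at 10 mg/L the matrix list had a median of 0.04 and an adjusted p of 0.696, with Eln at 0.12 and Col1a1 at 0.09. Without replicate 5 the median was 0.07 (adjusted p = 0.555) and Mmp9 stood at 0.39. Without replicate 3 the median was 0.30 and Eln 0.52. Leaving out replicate 4 at 10 mg/L (adjusted p = 0.177) or control replicate 2, 4, 6, 8 or 10 (adjusted p from 0.0556 to 0.220) also ended the call.

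The groups that were lower at 10 mg/L moved by less. Cell cycle genes fell as a list, with 22 of 24 members negative and a median of −0.08 (camera adjusted p = 0.00648, and adjusted p = 0.781 with an estimated correlation). Ccna2 at −0.16, Ccne2 at −0.29 (−0.17 without replicate 3 and −0.19 without replicate 5 at 10 mg/L) and Cdk1 at −0.15 were examples, and 0 of 24 passed over all genes or adjusted over the list alone. The median of this list was −0.04 without control replicate 4 (adjusted p = 0.0607) or without replicate 3 at 10 mg/L (adjusted p = 0.199), which ended its call, and −0.14 without replicate 4 at 10 mg/L. Nuclear genes of oxidative phosphorylation fell by a median of −0.04 with 18 of 22 negative (adjusted p = 0.0121, and adjusted p = 0.738 with an estimated correlation). Of these, Ndufb3 stood at −0.19, Ndufa1 at −0.25 and Cox5b at −0.15, and 0 of 22 passed over all genes or adjusted over the list alone. That call came from replicate 2 at 10 mg/L, without which the median was 0.02, the adjusted p 0.980, Ndufa1 −0.14 and Cox5b −0.08. The median was −0.02 without control replicate 8 and −0.08 without replicate 4 at 10 mg/L. Against the controls of experiment 2 alone Ndufb3 stood at −0.03 (SE 0.06) and Ndufa1 at −0.07 (SE 0.10). Both were higher in the controls of experiment 1, by 0.31 and 0.34. Genes of the integrated stress and unfolded protein responses fell by a median of −0.11 (adjusted p = 0.0312, and adjusted p = 0.738 with an estimated correlation), with the regulator Xbp1 at −0.29 and the disulfide isomerases Pdia4 at −0.16 and Pdia6 at −0.15. Their stress-induced factor Atf3, which is also an early response gene, stood at 1.00, and 0 of 19 passed over all genes or adjusted over the list alone. Without replicate 2 at 10 mg/L the adjusted p of that list was 0.298. Leaving out replicate 5 at 10 mg/L (adjusted p = 0.156), control replicate 2, 6 or 8 (adjusted p from 0.0560 to 0.0706) or replicate 5 at 500 mg/L (adjusted p = 0.101) also ended its call. The score of that list per mouse differed by only −0.0106, with 3 of 5 exposed mice above the control median (exact two-sided permutation p = 0.859), and by 0.00419 from the controls of experiment 2 (exact p = 0.952). Replicate 2 at 10 mg/L, on which the calls of the matrix, oxidative phosphorylation and stress lists depended, also stood apart in RNAs that lack a poly(A) tail, chosen after their values were seen: it had 47.2 CPM of the U1 RNA Rnu1a1, 35.9 CPM of Rmrp and 30.8 CPM of Rpph1, against at most 0.610, 1.14 and 0.865 CPM in the other 19 mice.

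The next comparison asked the same of 500 mg/L. Mid1 doubled again, to 43.3 ± 13.2 CPM (SD, n = 5), a log2 change of 1.01 (SE 0.16; edgeR adjusted p = 0.0220), and its lowest exposed value, 28.2 CPM, lay above the highest control value of 27.5 CPM. Tmsb15b1, an X-linked gene of the beta-thymosin family of actin monomer binding proteins, rose from 0.478 ± 0.137 CPM (SD, n = 10) to 1.94 ± 1.01 CPM (SD, n = 5), a log2 change of 2.02 (SE 0.30; edgeR adjusted p = 0.0220). It was higher in 5 of 5 exposed mice than in any control (lowest exposed 0.973 CPM, highest control 0.688 CPM). Its mean lay below the expression minimum of the rule for named genes, so it was chosen after its values were seen. No lower gene passed. The count at an unadjusted p under 0.05 was 1548, 744 of them lower, DESeq2 called 86 genes, and limma-trend and limma-voom called 0. Tmsb15b1 was not among the DESeq2 calls, since DESeq2 gave it no adjusted p. At 10 mg/L Tmsb15b1 differed by 1.34 (SE 0.31) and did not pass (edgeR adjusted p = 0.529), a difference between doses of 0.68 (SE 0.36; adjusted p = 0.541).

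Measured against the controls of experiment 1 alone, 0 genes passed at 500 mg/L by edgeR (924 at an unadjusted p under 0.05). Mid1 then stood at 1.04 (SE 0.19; edgeR adjusted p = 0.574) and Tmsb15b1 at 1.88 (SE 0.38; edgeR adjusted p = 0.732). When 1 library at a time was left out, Mid1 passed in 10 of 20 fits (adjusted p from 0.00563 to 0.141) and Tmsb15b1 in 12 of 20 (adjusted p from 0.0110 to 0.141).

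Immediate early genes rose as a list at 500 mg/L too (median log2 change 1.09, 17 of 18 positive, camera adjusted p = 0.00592, and adjusted p = 0.973 with an estimated correlation). Adjusted over the list alone 8 of 18 passed and over all genes 0 did, and the members with the smallest p were Fosb at 3.71, Atf3 at 1.48, Fos at 2.56 and the zinc finger factor Klf4 at 1.39. These values came from 1 mouse: replicate 5 at 500 mg/L had 1577 CPM of Fos, the lowest of the group had 24.8 CPM, and without replicate 5 the median of the list was −0.11 (adjusted p = 0.211), Fosb stood at −0.32, Atf3 at 0.12, Fos at −0.08 and Klf4 at −0.04. Only 2 of 5 exposed mice had a list score above the control median (exact two-sided permutation p = 0.390, adjusted p = 0.927).

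Antioxidant enzymes fell as a list at 500 mg/L by a median of −0.08, with 15 of 19 members negative (camera adjusted p = 0.0255, and adjusted p = 0.839 with an estimated correlation). Thioredoxin, encoded by Txn1, stood at −0.19, and the peroxiredoxin genes Prdx3 and Prdx1 at −0.17 and −0.16, while 0 of 19 passed over all genes or adjusted over the list alone. The scores of 4 of 5 exposed mice lay below the control median (exact two-sided permutation p = 0.0743, adjusted p = 0.927). Erythroid transcripts, which red cell precursors and blood carry, rose as a list by a median of 0.74 with 5 of 5 positive (adjusted p = 0.0411, and adjusted p = 0.839 with an estimated correlation). Alas2, the first enzyme of heme synthesis in red cells, stood at 1.16 and was the 1 of 5 that passed adjusted over the list alone, the globin genes Hba-a1 and Hbb-bs stood at 0.89 and 0.74, and 0 of 5 passed over all genes. Without replicate 2 at 500 mg/L Alas2 stood at 0.42. Leaving out replicate 4 at 500 mg/L ended the erythroid call, with a median of 0.43 (adjusted p = 0.142), Hba-a1 at 0.43 and Hbb-bs at 0.40. Replicate 5 (adjusted p = 0.108) and control replicates 3, 8, 9 and 10 (adjusted p from 0.0689 to 0.138) ended it in the same way. Endothelial markers did not pass at 500 mg/L, with a difference in score of 0.0530 (exact two-sided permutation p = 0.647).

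Setting the doses against each other asked what differed between 500 and 10 mg/L, a contrast that also holds the difference between experiments. Sfr1, a partner of recombination proteins in DNA repair, was higher at 500 mg/L, at 151 ± 10.1 CPM against 111 ± 5.44 CPM (SD, n = 5 each; log2 change 0.45, SE 0.07, edgeR adjusted p = 0.0457). Ifi27, an interferon-inducible mitochondrial protein gene, was lower, at 40.5 ± 2.67 CPM against 58.4 ± 6.64 CPM (SD, n = 5 each; log2 change −0.53, SE 0.09, edgeR adjusted p = 0.0457). In both genes the doses did not overlap, and no other gene passed (1788 at an unadjusted p under 0.05; 123 genes by DESeq2, 0 by limma-trend and limma-voom). Of the 20 fits that left out 1 library each, Sfr1 passed in 3 (adjusted p from 0.0290 to 0.186) and Ifi27 in 4 (adjusted p from 0.0290 to 0.168). The controls differed the same way: Sfr1 measured 138 ± 8.83 CPM in experiment 1 and 122 ± 6.78 CPM in experiment 2, and Ifi27 42.3 ± 3.99 CPM and 47.2 ± 3.33 CPM (SD, n = 5 each). With each dose set against the controls of its own experiment, the effects of the doses differed by 0.26 in Sfr1 (SE 0.08; edgeR adjusted p = 0.848) and by −0.37 in Ifi27 (SE 0.11; edgeR adjusted p = 0.831).

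**Figure D1:**
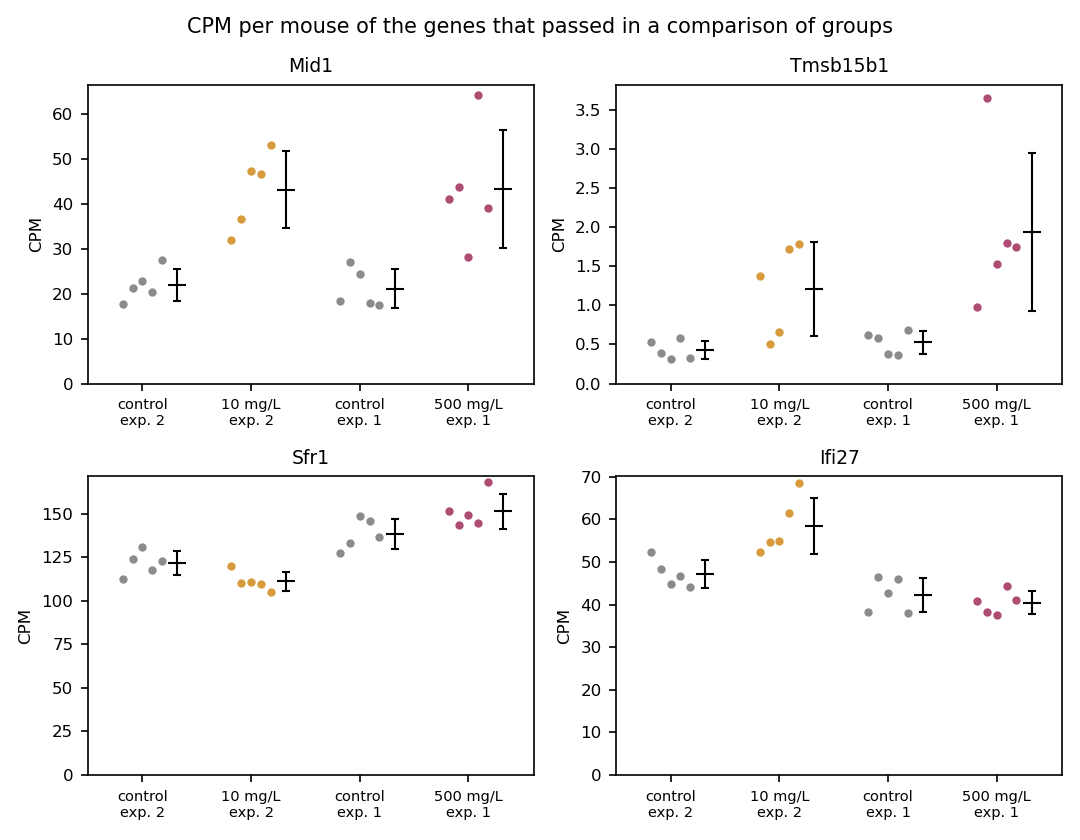
CPM of Mid1, Tmsb15b1, Sfr1 and Ifi27 (vertical axes) in each mouse, in columns for the controls and exposed mice of each experiment; points are mice, and the bar beside them is the mean ± SD (n = 5). Mid1 lay between 28.2 and 64.3 CPM in the exposed mice and between 17.6 and 27.5 CPM in the controls, whereas Sfr1 and Ifi27 also differed between the controls of the experiments.

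Among the gene groups, endothelial markers were lower as a list at 500 than at 10 mg/L, with 12 of 13 negative and a median of −0.20 (camera adjusted p = 0.000877, and adjusted p = 0.892 with an estimated correlation). Esam and the tight junction gene Cldn5 both stood at −0.43 and Tie1 at −0.37, and 0 of 13 passed over all genes or adjusted over the list alone. With own controls the list kept this direction (median −0.28, adjusted p = 0.000219, and adjusted p = 0.665 with an estimated correlation), but the exact permutation test of the difference in scores gave p = 0.255 (two-sided, adjusted p = 0.741). Leaving out replicate 5 at 10 mg/L (median −0.15, adjusted p = 0.0958) or replicate 3 at 500 mg/L (−0.15, adjusted p = 0.0651) ended the call. Nuclear genes of oxidative phosphorylation went both ways, with Ndufb3 at 0.33, Ndufa4 at −0.25 and Cox7c at 1.58, and 3 of 22 passed adjusted over the list alone and 0 over all genes. Ndufb3 and Cox7c also differed between the controls. Against own controls Ndufb3 stood at 0.02 (SE 0.08), Ndufa4 at −0.09 (SE 0.11) and Cox7c at −0.15 (SE 0.39).

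**Figure D2:**
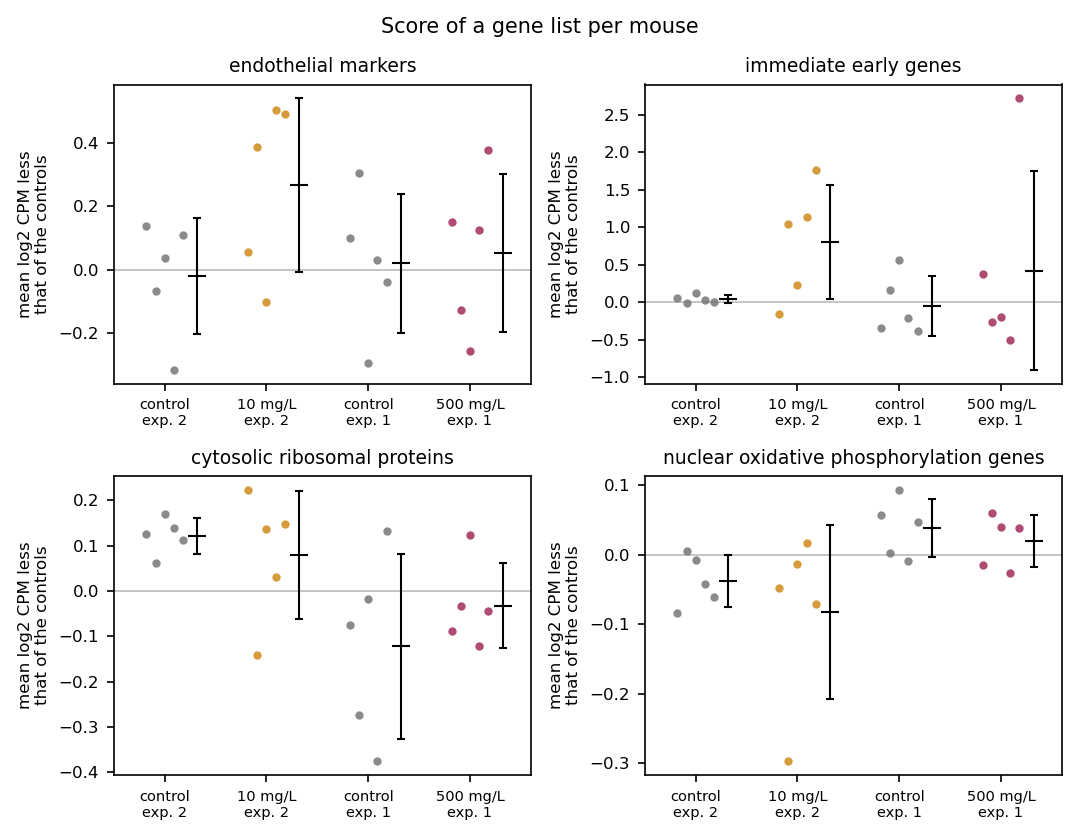
Score of 4 gene lists (mean log2 CPM of the members less that of the controls, vertical axes) in each mouse, in columns for the controls and exposed mice of each experiment; points are mice, and the bar beside them is the mean ± SD (n = 5). Replicate 5 at 500 mg/L reached 2.72 for immediate early genes and replicate 2 at 10 mg/L fell to −0.298 for nuclear oxidative phosphorylation genes, each far from the rest of its group.

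Over all groups of genes, the exact permutation test of scores per mouse passed for 0 of 32 lists after adjustment in each comparison, with 2 lists at an unadjusted p under 0.05 at 10 mg/L and 0 at 500 mg/L and between the doses. With 5 mice against 5 the smallest possible exact p was 0.00794, so 1 list alone could not pass after adjustment. The 0 between the doses, against own controls and between the control sets therefore says little. Against all 10 controls the smallest possible exact p was 0.000333. The difference between the effects of the doses, each against its own controls, likewise gave 0 genes by edgeR (964 at an unadjusted p under 0.05) and by limma-trend and limma-voom, and 15 by DESeq2. Both doses were measured against the same 10 controls, which by itself makes their log2 changes correlate over genes. That correlation was 0.220 (covariance 0.0153), and its mean was 0.331 (covariance 0.0217) in 20 simulated data sets without any change. The simulated mice had no difference between experiments, which in the real data pushes the doses apart, so the gap says nothing of a dose effect. With the controls split by experiment the correlation was −0.0885 with own controls and −0.179 with the controls exchanged, and no values without change were simulated for these. These correlations run across genes, which are not independent replicates. Of the calls, 1 gene, Mid1, was shared by the doses.

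Fitting a common effect of either dose with experiment as a term, added after the data had been seen, asked which genes differed on average over the experiments. A gene can pass this test through 1 experiment alone. Mid1 rose by 1.01 (SE 0.13, edgeR adjusted p = 0.00442) and Tmsb15b1 by 1.69 (SE 0.27, edgeR adjusted p = 0.0285). No lower gene passed (1212 genes at an unadjusted p under 0.05, 16 called by DESeq2, 1 each by limma-trend and limma-voom). Mid1 separated all 10 exposed mice from all 10 controls. Glo1, which encodes the glyoxalase that detoxifies methylglyoxal, differed by −0.82 (SE 0.16) and its chromosome 17 neighbour Btbd9 by −0.67 (SE 0.15) without passing (edgeR adjusted p = 0.324 and 0.397). Both were chosen after their values were seen. Glo1 had 189 ± 55.3 CPM in the controls (SD, n = 10), 110 ± 19.98 CPM at 10 mg/L and 104 ± 22.5 CPM at 500 mg/L (SD, n = 5 each).

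**Figure D3:**
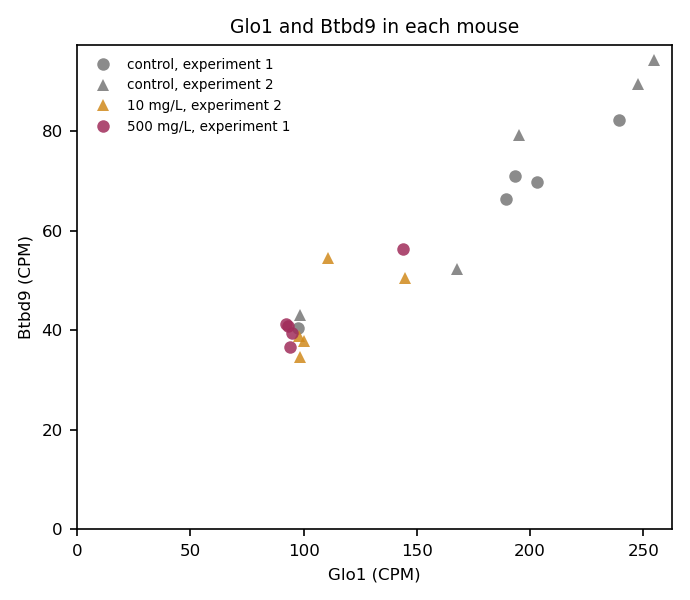
CPM of Btbd9 (vertical axis) against CPM of Glo1 (horizontal axis) in each of the 20 mice; colours are groups, circles are mice of experiment 1 and triangles mice of experiment 2. Glo1 ranged from 97.7 to 255 CPM in the controls, and the highest exposed mouse had 145 CPM.

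Comparing the controls of the experiments asked what differed without exposure. Here 28 genes passed, 14 higher and 14 lower in experiment 1 (edgeR; 1741 at an unadjusted p under 0.05; 192 genes by DESeq2), and 11 of the 28 were pseudogenes or predicted genes. Rpl34, a protein of the large ribosomal subunit, was lower in experiment 1, at 24.8 CPM against 51.9 CPM (log2 difference −1.06, SE 0.14, edgeR adjusted p = 0.00301). Its pseudogene Rpl34-ps1 held most reads of the family, at 331 CPM against 345 CPM, so it did not gain what Rpl34 lost. Their sum differed by −0.16. Also lower were Rps18 (−0.46, SE 0.09, adjusted p = 0.0490; −0.46 summed with its copy) and the pseudogene Rpl31-ps12, at 0.720 CPM against 61.4 CPM (−0.17 summed with Rpl31). Cox7c, a subunit of cytochrome c oxidase, was higher, at 23.6 CPM against 7.09 CPM (log2 difference 1.73, SE 0.29, adjusted p = 0.0214), as was the complex I subunit gene Ndufb3 (0.31, SE 0.06, adjusted p = 0.0326). The count went from 3 genes without control replicate 3 to 50 without replicate 2 at 10 mg/L.

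Cytosolic ribosomal protein genes were lower as a list in the controls of experiment 1 (median −0.21, 44 of 50 negative, camera adjusted p = 1.01e-24, and adjusted p = 0.808 with an estimated correlation). Of the 50, 18 fell adjusted over the list alone and 2 over all genes. Leukocyte markers stood higher in those controls by a median of 0.60 (17 of 18 positive, adjusted p = 1.13e-05, and adjusted p = 0.808 with an estimated correlation), with the antigen presentation genes H2-Ab1 at 1.12, H2-Aa at 0.88 and Cd74 at 0.91, and 0 of 18 passed over all genes or adjusted over the list alone. Oocyte markers were lower by a median of −0.26 (adjusted p = 9.53e-05, and adjusted p = 0.941 with an estimated correlation). The exact permutation tests of the scores gave p = 0.0317 for ribosomal proteins and p = 0.127 for leukocyte markers (two-sided, adjusted p = 0.508 for both). Set against own controls at 500 mg/L, leukocyte markers had a median of −0.53 (camera adjusted p = 3.78e-06, and adjusted p = 0.697 with an estimated correlation), and ribosomal protein genes 0.08 (adjusted p = 0.000344, and adjusted p = 0.697 with an estimated correlation), with exact permutation p of the scores of 0.190 and 0.429. At 10 mg/L the medians against own controls had the opposite signs, 0.21 (camera adjusted p = 0.251) and −0.05 (adjusted p = 0.00277, and adjusted p = 0.883 with an estimated correlation), with exact permutation p of 0.714 and 0.619.

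The authors' deposited table called more genes at an adjusted p under 0.05: 111 at 10 mg/L (46 higher, 65 lower), 229 at 500 mg/L (140 higher, 89 lower) and 289 between the doses (186 higher, 103 lower), of 18169 genes. Its adjusted p appear to be taken over the comparisons together, since Emcn at 10 mg/L and Rps14 between the doses share the value 0.0231. Here each contrast was adjusted alone, so the counts are not alike in threshold. The models differed too, with 2616, 3066 and 3309 genes at an unadjusted p under 0.05 in that table against 1108, 1548 and 1788 here. Its log2 changes correlated with those of the edgeR fit at 0.881, 0.884 and 0.900 across genes, and 110, 229 and 289 of its calls had the same direction there. By the authors' values Mid1 changed 1.97-fold at 10 mg/L (adjusted p = 0.0169) and 1.99-fold at 500 mg/L (adjusted p = 0.0164), and Tmsb15b1 2.16-fold at 10 mg/L (adjusted p = 0.0328) and 3.43-fold at 500 mg/L (adjusted p = 0.0111). Endothelial markers called in that table at 10 mg/L included Eng at 1.31-fold (adjusted p = 0.0141), Pecam1 at 1.23-fold (adjusted p = 0.0336) and Emcn at 1.22-fold (adjusted p = 0.0231), and 4 of 13 in all. Between the doses it called Sfr1 at 1.37-fold and Ifi27 at −1.42-fold (adjusted p = 0.0159 for both, a minus sign marking a fall), as well as Rpl34 at −1.98-fold (adjusted p = 0.0205), which also differed between the controls.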

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

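Chosen only after the result was seen were the count of exposed mice with raised immediate early genes, the tests on endothelial markers, and the check of whether the test on near-identical copies could decide. The share of a single gene and the scores of gene lists were searched for mice far from the rest of their group, by Dixon's criterion: 39 measures in 3 groups gave 117 sets of values, and chance marks about 1 in 20, here 5.85. In 7 sets a mouse stood apart.

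In replicate 2 at 10 mg/L the predicted gene LOC118568312 took 2.27% of all counts, while the top gene of the other mice of its group took 0.782% to 0.849%. The same mouse carried far more of the RNAs Rnu1a1, Rmrp and Rpph1, which lack a poly(A) tail, than any other. It also had a score of −0.298 for nuclear oxidative phosphorylation genes, against −0.0705 to 0.0166 in the rest of its group. Replicate 5 at 500 mg/L had a score of 2.72 for immediate early genes, against −0.506 to 0.372. Replicate 2 at 500 mg/L had −0.225 for NRF2 target genes, which answer to oxidants and electrophiles, against −0.0576 to 0.00347. Among the controls, replicate 4 had −0.281 for gonadotropin and steroid hormone receptors, against −0.0332 to 0.186. Control replicate 7 had 0.609 for stromal fibroblast markers, against −0.370 to 0.0759, and −0.209 for DNA repair genes, against −0.0560 to 0.0900.

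Immediate early genes were higher as a list at both doses, through some mice. The exposed mice above the control median of their own experiment were 7 of 10 (4 at 10 mg/L and 3 at 500 mg/L), and 3 and 1 of them lay above every control, too few mice to decide whether most exposed mice rose. Handling of the tissue before freezing may raise these genes, and they would then follow heat shock genes, but over the 20 mice their correlation within groups was 0.172 (Pearson; 95% interval −0.337 to 0.603, permutation p = 0.660, adjusted p = 0.660; Spearman's rho 0.104, p = 0.671; r = 0.0768 without the 2 mice farthest from the median), and it was 0.537 in experiment 1 and −0.745 in experiment 2, which leaves this open. Vessel or luteal cells dissected with the follicles stay open too, as the correlation with their scores was 0.338 (permutation p = 0.0717, adjusted p = 0.143; rho 0.394, p = 0.103; r = 0.375 without 2 mice; 0.307 and 0.545 by experiment). An effect of exposure, in part of the mice or in most, also stays open.

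Endothelial markers were higher at 10 mg/L in 4 of 5 mice. More tissue from outside the follicle would raise markers of stroma, pericytes and leukocytes alike, and the endothelial score less the mean of those scores was higher by 0.263 (exact two-sided permutation p = 0.0346), and by 0.184 against the controls of experiment 2 (exact p = 0.00794). Against all controls that mean is close to 0 because leukocyte markers went the other way, and less each score alone the endothelial score had exact p from 0.0556 to 0.124. Against the controls of experiment 2, scores of oviduct epithelium (0.260, exact permutation p = 0.0238, adjusted p = 0.734) and luteal cells (0.790, exact permutation p = 0.103) were higher too. Those of ovarian surface epithelium and adipocytes differed by −0.0356 and −0.143. More tissue from outside the follicle thus stays open. A difference between the experiments could not be excluded, because against the controls of experiment 2 alone the endothelial score differed by 0.287 with an exact p of 0.103, although the control sets differed by only 0.0394 (exact p = 0.754). More vessels in the theca layer, a change in the endothelial cells themselves and chance stay open, and none was tested on cells.

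Between the control sets 28 genes differed, 13 of them ribosomal protein genes, pseudogenes or predicted genes, and 1 of 100 splits of the controls, the real one, gave as many (at most 2 in the others), so chance can be excluded for the count of 28 but was not examined for that share. For the ribosomal list, transcript length, as degraded RNA would bring, is argued against: 0% of 10000 sets of genes matched for length and expression had a median as low as the −0.21 of the ribosomal list (lowest −0.11). The sets were drawn gene by gene, while members of a list can move together between mice. The 0% therefore measures spread over genes, not over mice. Reads shared between near-identical copies may explain part of it, and the families summed to 0.152 of the difference of their single genes, but the ratio would have been 0.136 had the other copies not moved, so this test could not decide. By family, summing changed little in Rps18 (−0.459 against −0.465 for the single gene) and Cox7c (1.729 against 1.731). In the families of Rpl34, Rpl31 and Rps15a the other copies together fell along with the called gene, which a transfer of reads would not give. In those of Rplp2, Tma7 and Llph the other copies together fell while the called one rose, as a transfer would give. Replicate 2 at 10 mg/L, without which 50 genes differed, did not look like a library of the other experiment: on the 15 genes that were neither ribosomal nor pseudogenes it lay at 0.0248 between the control sets (0 is its own experiment, 1 the other; the other 4 mice −0.327 to 0.124), against 0.444 on the other 13 (the other mice 0.00620 to 0.289). Month, mice, handling and library preparation cannot be told apart as sources of the difference between experiments.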

How the results depend on the processing

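Added after the data had been seen were surrogate variables without a limit on their number (5 were used), the effect of either dose with experiment as a term and its alternatives, the ontology and pathway terms, and the permutation tests of lists. Spread between mice limited the gene tests more than depth did. Mid1 kept its direction in all 14 other settings and all 20 fits without 1 library at each dose, and passed in 5 of the 14 at 10 mg/L and 7 at 500 mg/L. Tmsb15b1, Sfr1 and Ifi27 also kept their direction in each of these, and passed in 6, 6 and 5 of the 14 other settings.

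Counts of genes are given in the order 10 mg/L, 500 mg/L and 500 against 10 mg/L, where the main counts were 1, 2 and 2. DESeq2 called 8, 86 and 123. Limma-trend called 0, 0 and 0, limma-voom 0, 0 and 0, a fold threshold of 1.2 gave 0, 0 and 0, and limma-trend with unlimited surrogate variables gave 0, 0 and 0. With up to 3 surrogate variables the counts were 0, 0 and 7. Each dose against its own controls gave 0, 0 and 0, and against the controls of the other experiment 21, 170 and 353, where the difference between experiments enters. The replicate block gave 0, 17 and 8, although the replicate numbers do not pair the mice (correlations of −0.169 to 0.228 between mice of the same number). Upper-quartile factors and no filter each gave 0 at 10 mg/L and 0 between the doses, and only the groups compared gave 0 between the doses. Between the control sets, 28 genes became 11 with no filter, 48 with at least 1 CPM in at least 5 mice, 192 with DESeq2 and 3 with a fold threshold of 1.2. The difference between dose effects went from 0 to 15 with DESeq2. Either dose went from 2 to 16 with DESeq2, 1 with limma-trend and 1 with limma-voom. Except for the controls exchanged, where the construction adds the experiment, the cause was not tested.

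Lists passed in numbers of 7, 3 and 1. An estimated correlation left 0, 0 and 0, each dose with its own controls gave 5 at 500 mg/L and 11 between the doses, the replicate block gave 1 and 5, and DESeq2 size factors gave 3 between the doses. Terms passed in numbers of 22, 17 and 30, with an estimated correlation 0, 0 and 0, and with own controls 39 at 500 mg/L and 68 between the doses. Cox7c between the doses reversed to −0.15 with own controls.

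Leaving out 1 library at a time, the counts of genes ran from 0 to 1 at 10 mg/L, 0 to 3 at 500 mg/L, 0 to 4 between the doses, 3 to 50 between the control sets, 0 to 0 for the difference between dose effects and 1 to 3 for either dose. Lists ran from 5 to 9, 2 to 6 and 0 to 5, and terms from 0 to 83, 6 to 27 and 0 to 74. At 500 mg/L the median of immediate early genes ran from −0.11 to 1.34, Fosb from −0.32 to 4.27, Fos from −0.083 to 2.86 and Klf4 from −0.035 to 1.61, each lowest without replicate 5.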

Other observations

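The ontology and pathway terms, the effect of either dose, the splits within 1 experiment, the count of genes without overlap and the test on copies of Tmsb15b1 were chosen only after results had been seen. At 10 mg/L, 22 of 2806 terms passed, 20 of them lower, and mRNA splicing via the spliceosome (median log2 change −0.05, 38 of 141 genes positive, camera adjusted p = 0.00345), protein processing in the endoplasmic reticulum (−0.06, 44 of 161 positive, adjusted p = 0.00345) and protein folding (−0.05, 27 of 98 positive, adjusted p = 0.00469) were among them. Leaving out control replicate 4 (adjusted p = 0.101, 0.0510 and 0.101) or replicate 5 at 10 mg/L (0.564, 0.237 and 0.4004) ended the call of each, and control replicate 8 that of splicing (0.102) and folding (0.0524). The median of splicing was −0.03 without control replicate 8 or replicate 5 at 10 mg/L, and that of folding −0.04 without replicate 2 at 10 mg/L. At 500 mg/L, 17 passed: oxidative phosphorylation was lower (−0.07, 26 of 114 positive, adjusted p = 0.000344), and centriole (0.08, 84 of 114 positive, adjusted p = 0.00134; 0.05 without replicate 2 at 500 mg/L) and microtubule motor activity (0.10, 38 of 47 positive, adjusted p = 0.00515) were higher. The fixed list of nuclear oxidative phosphorylation genes did not pass at 500 mg/L, with a difference in score of 0.0193 and 3 of 5 mice above the control median (exact two-sided permutation p = 0.495). Between the doses 30 passed, and splicing was higher at 500 mg/L (0.06, adjusted p = 0.00101; 0.170 without replicate 5 at 10 mg/L). With an estimated correlation 0 terms passed, and the smallest adjusted p was 0.995, 0.9998 and 0.996.

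Chance was examined by 100 splits of the mice into groups of the same sizes. For the 2 genes at 500 mg/L, 3 splits were as large (at most 19 in the others). That share is under 0.05, but it is not adjusted for the number of counts examined. These splits mixed mice of both experiments, while the mice at 500 mg/L were all of experiment 1, so they do not exclude chance. Chance cannot be excluded either for the 1 gene at 10 mg/L (9 splits, at most 24) or the 2 genes between the doses (6 splits, at most 859). The split with 19 genes took its 5 mice from experiment 1. Mice were then exchanged only within the experiment of the dose, so that the experiments stayed as they were. At 500 mg/L 3 of 100 splits gave as many genes (2 against at most 8), again a share under 0.05 without adjustment. At 10 mg/L 8 did (1 against at most 3). Chance is thus excluded at neither dose. The shares do not rank the doses, since they count splits with at least 2 genes at 500 mg/L and at least 1 at 10 mg/L. Against the controls of experiment 1 alone the count at 500 mg/L was 0 by edgeR (924 at an unadjusted p under 0.05). For the 2 genes of either dose 3 splits within experiments gave as many (at most 9). That share is also not adjusted, and it leaves out that this effect was chosen after both genes had been called. Splits with as many as 859 genes may reflect a structure of the mice, but none was identified or tested. The split with 859 took 40% of its first group from experiment 2, and the next highest count was 132. The difference between dose effects gave 0 genes, which all 100 splits equalled or exceeded (at most 480). Lists passed as often in 70 splits at 10 mg/L (7 against at most 19), 95 at 500 mg/L (3 against 21) and 100 between the doses (1 against 19), and terms in 74 (22 against 555), 75 (17 against 634) and 67 (30 against 554), so chance cannot be excluded for these counts, and the shifts of gene groups are best read as descriptions.

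Mid1 alone separated all exposed mice from all controls, but 11 of 100 splits gave at least 1 such gene (at most 2), so that chance cannot be excluded for this count by itself. A structural variant in an outbred stock might change the chromosomal neighbourhood of Mid1 on both sides. That is argued against by a median difference of 0.16 over the 6 tested genes of the 15 nearest (−0.09 to 0.62), with 1 over 0.5. The tested genes on the side of the pseudoautosomal region, the predicted gene G530011O06Rik at 0.62 and Erdr1 at 0.24, were both higher. A variant that reaches only to that side, into the pseudoautosomal region, therefore stays open. A variant of Mid1 itself was not tested. It could be examined by genotyping the mice at Mid1, whose end reaches into that region.

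Tmsb15b1 has near-identical copies, and a shift of reads from them might raise it. The copies Tmsb15b1, Tmsb15b2 and Tmsb15l together gained 6.85 times the CPM that Tmsb15b1 gained (7.51, SE 3.54, against 1.10, SE 0.27). That argues against a net loss by the others. The SE of the sum exceeds the gain of Tmsb15b1, so reads shifted to it within a rise of the whole family would not show. A higher level of the whole family in exposed mice, which the spread of Tmsb15l leaves open (gain 5.65 CPM, SE 2.87; by the authors' values 1.39-fold at 500 mg/L, adjusted p = 0.0159), could be examined by PCR specific to each copy.

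Glo1 and Btbd9 were lower in exposed mice without passing. Some mouse strains carry a duplication that spans Glo1 and parts of its neighbours, and its number of copies may have differed between these outbred mice. Within groups, Btbd9 ranked 1 among all tested genes by correlation with Glo1 (Pearson r = 0.927, Spearman's rho 0.877, both with p = 1e-05, the smallest the permutations can give; r = 0.871 without the 2 mice farthest from the median; 0.984 in experiment 1 and 0.893 in experiment 2), the neighbour Glp1r ranked 2 (r = 0.811) and Dnah8 ranked 6 (r = 0.699), all on chromosome 17. The predicted pseudogene Gm6402, which lies between Glo1 and Btbd9, ranked only 4443 (r = 0.196), and Zfand3, beyond Btbd9, ranked 9695. Inherited copies of the locus, an uneven share of which among the groups would mimic an effect of exposure, are thus possible but untested, and genotyping the duplication would examine them.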
